A study of Homo sapiens with 12 samples.

How the data were processed

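Total RNA of 12 samples was measured by ribodepleted RNA sequencing: 3 replicates each of H9 wild type cultures and of 3 HSF1 knockout clones, harvested at day 25 of a 3D cardiomyocyte differentiation. H9 is an established human embryonic stem cell line. The labels describe the replicates as independent, but do not say whether replicate numbers are shared between groups, nor the date, batch or edit of any sample. The genotype label reads wild type for all 12 samples, so groups were taken from the sample titles, which name the clones. The deposited table holds raw counts of fragments per gene name, 1 column per library, and, per the file headers, the summed exon length of each gene. Per the file headers these were made with featureCounts version 2.0.1 on read pairs (summarised by gene name against GENCODE 33), without options for strand, multi-mapped reads or reads shared between genes. Per the submitters' processing notes the genome was hg38 and FastQC, STAR and DESeq2 were also used, with no versions given. Counting without strand adds antisense reads, a read over 2 genes is dropped, and a read with several places is not counted, which lowers genes with near-identical copies. The share of each named gene's exon length that other genes overlap was computed from the coordinates of the table.

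The table was read in R version 4.3.3. Genes with too few counts for the group size were removed with the filterByExpr function of edgeR version 4.0.16, which kept 24121 of 60583 genes and dropped 0.45% of all counts. Library sizes were scaled with TMM factors, and a quasi-likelihood model with 4 groups was fitted to all 12 libraries (glmQLFit and glmQLFTest). Contrasts were each clone minus WT, the mean of the 3 clones minus WT, and any difference between clones on 2 degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called higher or lower, and all tests were 2-sided. Adjusted p values for single genes come from edgeR unless another tool is named. Fold changes are log2 values with standard errors, and levels are TMM-scaled CPM with the SD over 3 libraries. A fold against a group with 0 counts used a floor of 3 counts over the group and is a lower bound, and genes with 1 to 3 counts are given with an exact 95% interval of the ratio. Per library, 3 counts are 0.242 to 0.671 CPM of the raw total, before TMM scaling. Intervals and floors cover counting error only.

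The 42 gene lists, the named genes rule, the tests and the alternatives were fixed before the data were examined. Lists were tested with camera in limma version 3.58.1 on voom values with a preset correlation of 0.01, with camera using an estimated correlation and with fry beside it, adjusted over the lists. A count adjusted over the list alone repeats the Benjamini-Hochberg step within a list. No list passed with an estimated correlation in any comparison, where the lowest adjusted p was 0.32 in KO-1, 0.16 in KO-2, 0.20 in KO-3 and 0.15 in the mean. Camera passed 28, 14, 34 and 23 of 42 lists in these comparisons, and fry passed 6, 4, 33 and 21. The rule took HSF1, HSF2 and HSF4. For the mean of the clones it took the 8 largest rises and 8 largest falls with every KO library outside the WT range and a mean log2 CPM of 1 or more, and for each clone the 3 largest. It also took up to 4 members per list with the smallest p and the 5 genes with the smallest p between clones. ICAM1, TNFAIP3, NFKBIA, ZC3HAV1L, PXMP4 and CCDC169 lie outside the rule and were chosen after their values were seen, as were the lists of NF-kB targets, forebrain and eye field genes and leukocyte genes.

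The pipeline was tested on simulated data with 100 genes changed per fold. With 23669 genes run, the mean comparison recovered 49% of genes changed 2-fold and 90% of those changed 4-fold. KO-1 recovered 34% and 81%, KO-2 32% and 82%, and KO-3 35% and 84%. The test between clones recovered 35% and 80% of genes changed in KO-3 only, with 23645 genes run. With nothing changed, 0 of 23653 genes were called in any comparison. With genes changed in all clones, 13 of 152 genes called in the mean were unchanged ones. It was 4 of 119 in KO-1, 8 of 122 in KO-2 and 11 of 130 in KO-3. The share of false calls thus exceeded 5% in the mean, KO-2 and KO-3. The test between clones, with KO-3 changed only, gave 5 of 120. Alternatives were DESeq2 version 1.42.0, RLE factors, factors without mitochondrial and the 20 most abundant genes, no filter and a stricter filter, a replicate block, a 1.5-fold minimum (glmTreat), leaving out each library, 6-library fits, the clone as a random block in limma, 2-clone means and a 2-group fit. A fit without KO-1 library 3 and KO-2 libraries 1 and 2 was added after seeing the data. Figures were drawn with matplotlib. Results for 3 single genes are not reported here. Sex chromosome genes that differ between the sexes were not examined.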

Results

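Gene expression was measured in cardiomyocyte cultures from clones described as knockouts of HSF1, the transcription factor that drives the heat shock response, to learn how they differ from the unedited line. The cells were H9, an established human embryonic stem cell line, and 3 HSF1 knockout (KO) clones of it, named KO-1, KO-2 and KO-3. Each was taken through a 3D cardiomyocyte differentiation and sampled at day 25. Ribosomal RNA was depleted from total RNA and 1 library was sequenced from each of 3 replicates per group, 12 in all, so that 9 KO libraries stood against 3 of unedited wild type (WT). The libraries held 4470141 counts (KO-2 library 1) to 12398938 counts (WT library 1). Expression was tested for 24121 of 60583 genes.

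The targeted gene, HSF1 (chromosome 8, 144291591 to 144314720, hg38, protein coding), was expressed in all 12 libraries. Its level was 115 ± 3.2 TMM-scaled CPM in WT (SD, n = 3), 71.2 ± 5.3 in KO-1, 90.0 ± 31.5 in KO-2 and 40.5 ± 6.01 in KO-3. In KO-2, libraries 1, 2 and 3 read 96.4, 118 and 55.9 CPM, against 111 to 117 in WT. HSF1 fell in KO-3 (log2 fold change −1.51 ± 0.21 SE, edgeR adjusted p = 0.00013) and in the mean of the 3 clones (−0.85 ± 0.16, adjusted p = 0.0022), and 8 of the 9 KO libraries lay below every WT library. KO-1 (−0.69 ± 0.20, adjusted p = 0.062) and KO-2 (−0.36 ± 0.20, adjusted p = 0.23) did not pass the test at 5%. KO-2 stood at −0.60 without its library 2 and at −0.10 without its library 3, and passed in neither. With KO-1 library 3 and KO-2 libraries 1 and 2 left out, KO-2 (n = 1) was at −1.03. KO-1 passed the test with DESeq2 (adjusted p = 0.033) and in an edgeR fit of the 6 KO-1 and WT libraries (adjusted p = 0.0025). In edgeR it also passed with a replicate block (adjusted p = 0.0498), with no filter (0.0051) and without KO-2 library 2 (0.029) or 3 (0.0014). It did not pass in the other alternatives fixed before, among them leaving out any WT or KO-1 library (edgeR adjusted p = 0.091 to 0.216). The call on the mean ended without KO-3 (−0.51, adjusted p = 0.14), with the clone as a random block (−0.92, adjusted p = 0.46), with all KO libraries as 1 group (−0.78, adjusted p = 0.15) and against a 1.5-fold minimum (adjusted p = 0.21). The labels do not give the edit, and a count over the whole gene reads neither frame nor protein. HSF2, a related heat shock factor, was at 60.7 ± 3.0 CPM in WT and rose in KO-2 (0.53 ± 0.16, adjusted p = 0.043), with 84.5, 113 and 64.9 CPM in its libraries against 57.6 to 63.7 in WT. HSF4, another family member with 31.4% of its exon length shared with other genes, fell in KO-3 (−1.73 ± 0.42, adjusted p = 0.0063) and rose in KO-2 (1.22 ± 0.37, adjusted p = 0.040). The latter rise rests on KO-2 libraries 1 and 2 (7.41 and 13.6 CPM), as library 3 (4.39) lay within the WT range of 2.91 to 4.80.

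**Figure D1:**
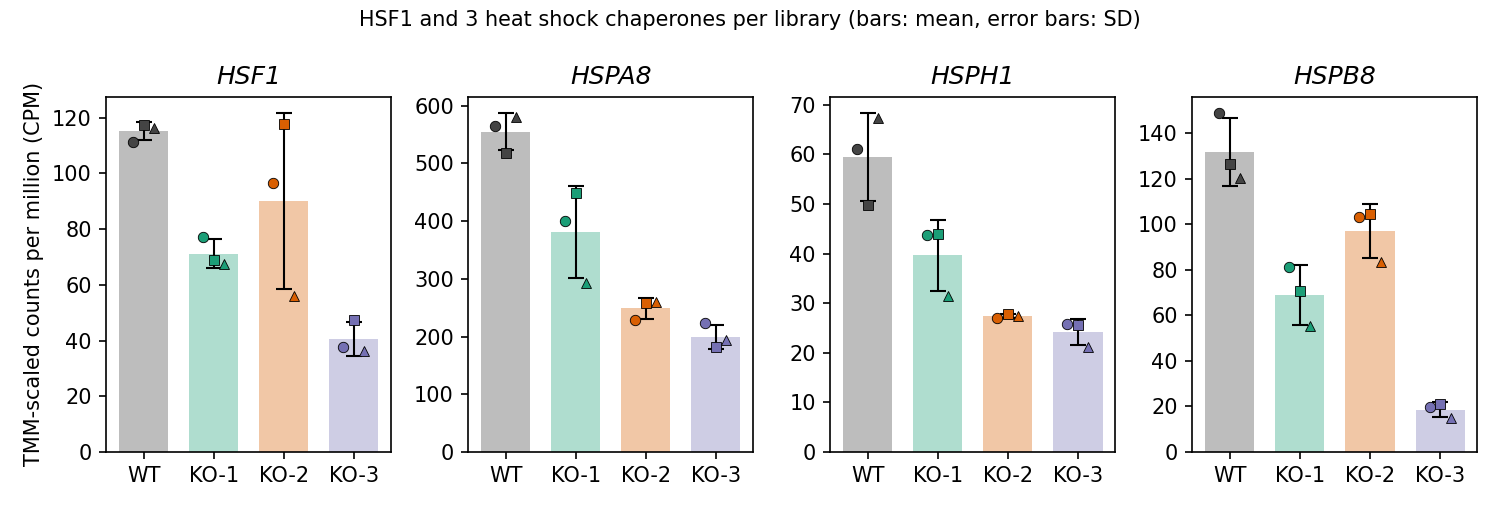
TMM-scaled CPM of HSF1, HSPA8, HSPH1 and HSPB8 in each group, with bars for the mean, error bars for the SD of 3 libraries, and circles, squares and triangles for libraries 1, 2 and 3. HSF1 in KO-2 ranged from 55.9 to 118, while HSPA8 lay below every WT library in 9 of 9 KO libraries.

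The mean of the 3 clones against WT asked what the HSF1 knockouts had in common on average. Heat shock chaperones were lower: HSPA8, the constitutive HSP70, went from 555 ± 32 CPM in WT to 381 ± 79.5 in KO-1, 249 ± 18 in KO-2 and 200 ± 21 in KO-3 (SD, n = 3 each), a mean log2 change of −1.06 ± 0.11 SE. HSPH1, an HSP110 co-chaperone, fell from 59.4 ± 8.86 CPM in WT to 39.7 ± 7.18 in KO-1, 27.4 ± 0.379 in KO-2 and 24.2 ± 2.53 in KO-3. HSPB8, a small heat shock protein, fell by 1.40 ± 0.12, and all 3 lay below every WT library in 9 of 9 KO libraries (adjusted p = 7.4e-05 or lower). Of 32 measured heat shock response chaperones, 14 fell, 0 rose and 18 did not pass (16 fell and 1 rose adjusted over the list alone). The list was lower by camera (adjusted p = 1e-05; adjusted p = 0.37 with an estimated correlation). Among 13 small heat shock proteins and muscle co-chaperones, 10 fell and 3 did not pass, with 10 adjusted over the list alone. This was largely through KO-3, as 1 fell in KO-1, 1 fell and 1 rose in KO-2, and 12 fell in KO-3. Their medians in KO-3 libraries 1, 2 and 3 (−2.66, −1.87 and −2.84) lay near those of the sarcomere genes (−2.79, −2.06 and −3.21). The fall of these 13 genes therefore cannot be told apart from that of muscle genes in general. HSPB3, a muscle small heat shock protein, fell by 1.86 ± 0.24, and UNC45B, the myosin chaperone, by 1.19 ± 0.22. Neither passed without KO-3, where HSPB3 stood at −0.95 (edgeR adjusted p = 0.063) and UNC45B at −0.25 (edgeR adjusted p = 0.55). This list was also lower by camera (adjusted p = 1e-05, and adjusted p = 0.37 with an estimated correlation). With the clone as a random block 0 genes of either list passed although the list medians hardly moved (−0.30 against −0.29 and −0.91 against −0.88). HSPA8 was then at −1.06 (adjusted p = 0.147), HSPH1 at −0.99 (0.133) and HSPB8 at −1.49 (0.404).

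Liver and endoderm transcripts fell further than any other list in the mean of the clones. APOC3, an apolipoprotein of liver and gut, was at 171 ± 20 CPM in WT, 60.1 ± 24 in KO-1, 7.23 ± 4.7 in KO-2 and 1.36 ± 0.88 in KO-3, and fell by 4.32 ± 0.28 on the log2 scale. HNF4A, a hepatocyte transcription factor, fell by 3.37 ± 0.21, RBP4, the retinol carrier, fell by 4.19 ± 0.28 and VTN, the plasma protein vitronectin, fell by 3.07 ± 0.21, each below every WT library in 9 of 9 KO libraries. Of the 26 endoderm and hepatic markers, 25 fell and 1 rose, as they did adjusted over the list alone (median −2.92; camera adjusted p = 3.3e-24; adjusted p = 0.15 with an estimated correlation). Endothelial markers fell as well, 14 of 18, with 14 adjusted over the list alone (median −0.89; camera adjusted p = 4.7e-09; adjusted p = 0.30 with an estimated correlation). FLT1, a VEGF receptor, fell by 1.58 ± 0.11, and KDR, another VEGF receptor, by 1.08 ± 0.14.

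Neural markers rose. SOX2, a transcription factor of neural progenitors and pluripotent cells, was at 15.9 ± 1.3 CPM in WT, 86.9 ± 71 in KO-1, 46.4 ± 14 in KO-2 and 170 ± 18 in KO-3, a mean log2 rise of 2.46 ± 0.38 (adjusted p = 0.00063). PAX2, a transcription factor of eye, ear and kidney development, rose by 3.86 ± 0.41. FGF19, a secreted growth factor expressed in the developing brain and gut, rose by 4.32 ± 0.59. Both lay above every WT library in 9 of 9 KO libraries, which the rule that named them required. Of 19 neural and neural crest markers, 10 rose and 0 fell (13 rose adjusted over the list alone; camera adjusted p = 2e-06; adjusted p = 0.37 with an estimated correlation). In KO-1 the level varied between libraries: SOX2 was at 43.9 and 48.3 CPM in KO-1 libraries 1 and 2 and at 168 in library 3. The mean calls on SOX2 and on VAX1, a forebrain transcription factor, held without KO-1 library 3. VAX1 had a mean log2 rise of 3.79 ± 0.79 and no longer passed without KO-3 (2.86, adjusted p = 0.10 over the other clones).

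Contractile and metabolic genes of the cardiomyocyte were lower in the mean, largely through KO-3. Of 32 sarcomere genes, 19 fell and 13 did not pass (21 fell adjusted over the list alone; camera adjusted p = 3.1e-09; adjusted p = 0.37 with an estimated correlation), but 3 fell in KO-1, 0 in KO-2 and 26 in KO-3. TPM1, a tropomyosin of the thin filament, was at 1601 ± 119 CPM in WT, 948 ± 129 in KO-1, 1456 ± 269 in KO-2 and 418 ± 86.3 in KO-3. MYL7, the atrial myosin light chain, fell by 1.10 ± 0.22 in the mean and stood at 0.02 (adjusted p = 0.96) without KO-3. Of 24 cardiac transcription factors, 14 fell and 1 rose (15 and 1 adjusted over the list alone; camera adjusted p = 2e-07; adjusted p = 0.30 with an estimated correlation); HAND1, a factor of heart chamber development, fell by 2.03 ± 0.22. Among 18 calcium handling genes, 13 fell and 1 rose (15 and 1 adjusted over the list alone; camera adjusted p = 3e-07; adjusted p = 0.31 with an estimated correlation). SLN, the SERCA regulator sarcolipin, fell by 3.77 ± 0.30 and was lower in each clone. In oxidative phosphorylation, 25 of 40 nuclear genes fell and 1 rose (30 and 1 adjusted over the list alone; camera adjusted p = 1.7e-08; adjusted p = 0.37 with an estimated correlation). In fatty acid oxidation 18 of 28 fell (21 adjusted over the list alone; camera adjusted p = 1.4e-08; adjusted p = 0.26 with an estimated correlation), among them CPT1A, the gate of mitochondrial fatty acid import (−0.99 ± 0.12).

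A small set of genes was near silent in every KO library. H4C13, a replication-dependent histone H4 gene, had 378 counts in the WT libraries and 2 in the 9 KO libraries together, 0.23% of the WT level (95% exact interval 0.0278 to 0.838). H3C3, a histone H3 gene, had 605 against 11 (0.791%, 0.393 to 1.43), S100A6, a calcium-binding protein, 955 against 12 (0.547%, 0.282 to 0.96), TRIM4, a ubiquitin ligase, 270 against 6 (0.967%, 0.352 to 2.13), and TMEM176A, a membrane protein, 481 against 11 (0.995%, 0.494 to 1.8). These intervals cover counting error only. Reads that map to several places were not counted, so histone genes with near-identical copies are measured on their unique part. The 5 genes fell in each clone and passed in the mean with the clone as a random block, the coordinates being chromosome 6, 27873199 to 27873510 for H4C13 and chromosome 1, 153534599 to 153536244 for S100A6.

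In the mean comparison 5055 genes passed the threshold of 5% in edgeR, 1934 higher and 3121 lower. The 9 KO libraries come from 3 clones and the WT libraries from 1 line, so the test reads the spread between differentiations. With the clone as a random block 158 genes passed, 6 of them higher, and without KO-3 1284 passed. Of the lists above, 6 hepatic markers and 1 calcium handling gene fell with that block, and 0 genes passed among the endothelial, neural, sarcomere, cardiac transcription factor, oxidative phosphorylation and fatty acid oxidation lists. Their medians under the block were −0.90, 1.36, −0.95, −0.94, −0.41 and −0.51, against −0.89, 1.48, −0.96, −0.90, −0.38 and −0.49. The count was 1163 against a 1.5-fold minimum, 1079 with all KO libraries as 1 group and 9813 without KO-2. Without WT library 1, 2 or 3 it was 2611, 3362 or 2872, and without KO-2 library 3 it was 9339.

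**Figure D2:**
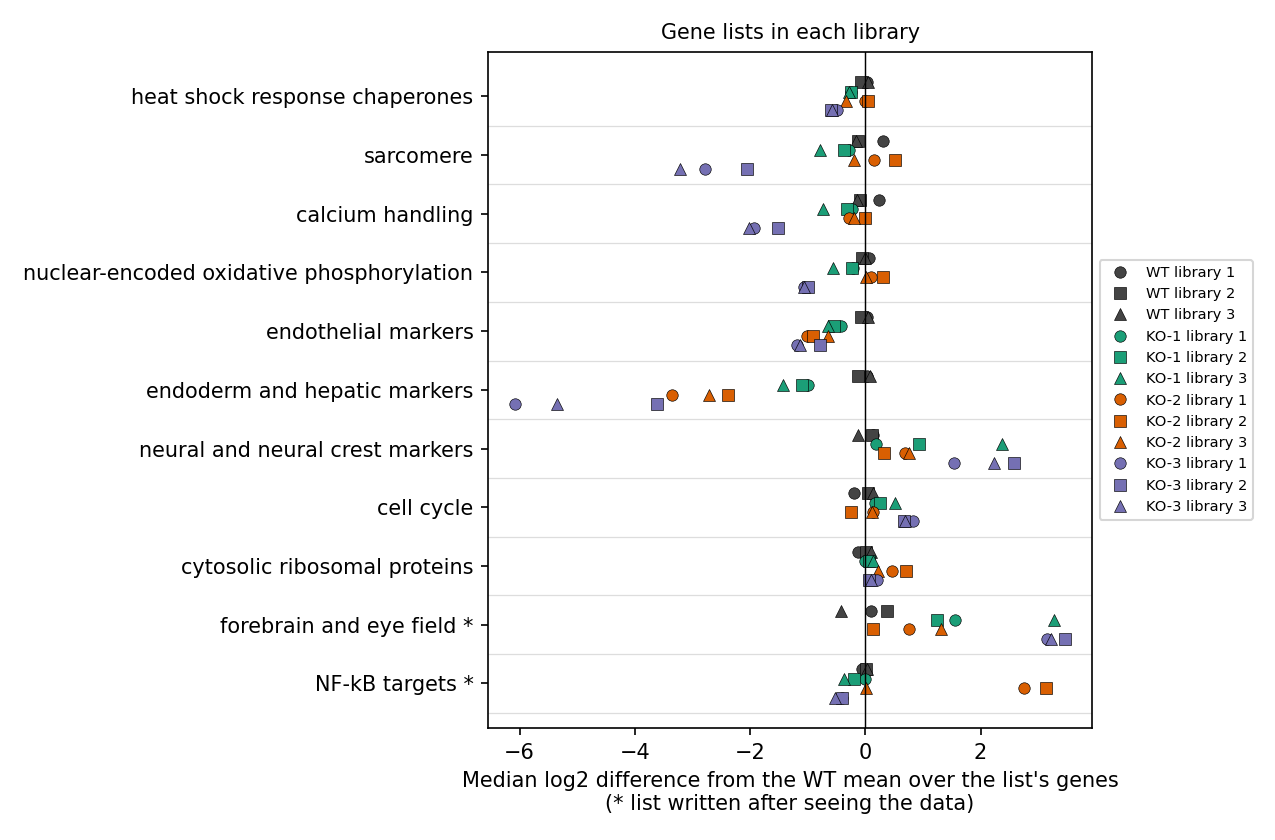
Median log2 difference from the WT mean over the genes of each list, on the horizontal axis, for every library, with colours for groups and symbols for libraries 1 to 3. Hepatic markers lay below WT in all 9 KO libraries, the NF-kB list stood at 2.75 and 3.14 in KO-2 libraries 1 and 2 and between −0.52 and 0.03 in the others, and the 2 lists marked with a star were written after the data had been seen.

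The comparison of KO-1 with WT asked what 1 clone showed on its own. Hepatic transcripts were lower in KO-1: RBP4 fell by 2.12 ± 0.35 and VTN by 1.78 ± 0.28, and 13 of 26 markers fell (20 fell and 1 rose adjusted over the list alone; camera adjusted p = 2.8e-18; adjusted p = 0.32 with an estimated correlation). Of the 32 heat shock chaperones 3 fell, namely HSPA8 (−0.54 ± 0.15), HSPH1 (−0.58 ± 0.15) and HSPB8 (−0.93 ± 0.16), with 8 fallen and 1 risen adjusted over the list alone (camera adjusted p = 4.5e-05; adjusted p = 0.45 with an estimated correlation). TGFBI, a secreted matrix protein, fell by 2.12 ± 0.25, and 7 of 34 extracellular matrix genes fell (17 fell and 1 rose adjusted over the list alone; camera adjusted p = 1.5e-07; adjusted p = 0.42 with an estimated correlation). Among them FN1, which encodes fibronectin, went from 5250 ± 844 CPM in WT to 2219 ± 487. OR8D1, an olfactory receptor gene, had 408 counts in KO-1 and 25 in WT, 20.7-fold higher at equal depth (95% exact interval 13.8 to 32.3). Of 19 neural markers 8 rose (11 adjusted over the list alone; camera adjusted p = 2.4e-06; adjusted p = 0.42 with an estimated correlation), and the list median was 1.55, or 0.57 without KO-1 library 3 and KO-2 libraries 1 and 2. Without KO-1 library 3 alone, 6 hepatic markers, 1 chaperone and 3 matrix genes fell and 5 neural markers rose, and without KO-2 library 3, 10 chaperones and 15 matrix genes fell.

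In KO-1, 657 genes were higher and 823 lower, 1480 in all. KO-1 library 3 correlated slightly better with a KO-3 library (r = 0.975 over genes) than with KO-1 libraries 1 and 2 (0.969 and 0.971), which reached r = 0.985 with each other; genes are not independent replicates. The count was 612, 832 or 558 without WT library 1, 2 or 3, 590 without KO-1 library 3, 3643 without KO-2 library 3, and 2484 without the 3 libraries named above. DESeq2 gave 2239, the 6-library fit 2652 and a 1.5-fold minimum 313.

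KO-2 against WT asked the same of a second clone. Hepatic markers fell by a median of 2.72, with 23 of 26 past the threshold (25 adjusted over the list alone; camera adjusted p = 1e-23; adjusted p = 0.16 with an estimated correlation), and RBP4 fell by 4.32 ± 0.42. HSPA8 fell by 1.16 ± 0.15 and HSPH1 by 1.11 ± 0.15; of 32 chaperones 6 fell and 1 rose (9 and 2 adjusted over the list alone; camera adjusted p = 0.20), and without KO-2 library 3 the list gave 8 fallen and 10 risen. Of 18 endothelial markers 12 fell (13 adjusted over the list alone; camera adjusted p = 9.9e-08; adjusted p = 0.83 with an estimated correlation), with CDH5, the endothelial cadherin, at −1.01 ± 0.16. MPV17L, a peroxisomal protein gene, had 0 counts in all 3 KO-2 libraries and 262 in WT, at least 48.1-fold lower against a floor of 3 counts over the group. PKIB, a protein kinase A inhibitor, fell by 2.74 ± 0.23.

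Libraries 1 and 2 of KO-2 stood apart from every other library, and several KO-2 changes moved with them. KO-2 library 3 correlated with them at r = 0.936 and 0.933 and with KO-1 library 1 at 0.979. Their list medians for NF-kB targets, a list written after the data were seen, were 2.75 and 3.14, and 20 of 23 measured members rose in KO-2. CXCL2, a chemokine, was at 68.3 and 87.8 CPM in these 2 libraries, 1.42 in KO-2 library 3 and 0.928 to 1.35 in WT. Ribosomal protein genes rose (33 of 38, 37 adjusted over the list alone; camera adjusted p = 6.5e-18; adjusted p = 0.83 with an estimated correlation). Hypoxia genes rose in KO-2, 8 of 16 (11 adjusted over the list alone), with VEGFA, the endothelial growth factor, at 2509 and 2782 CPM in libraries 1 and 2 and 802 in library 3, and 7 of 24 glycolysis genes rose (16 adjusted over the list alone). The p53 targets gave 8 risen and 1 fallen of 20 (10 and 1 adjusted over the list alone) and cholesterol synthesis 8 risen and 2 fallen of 20 (14 and 2 adjusted over the list alone). Camera gave these 4 lists adjusted p values of 0.00044, 9.9e-06, 0.00088 and 0.011, each with adjusted p = 0.83 with an estimated correlation. With KO-1 library 3 and KO-2 libraries 1 and 2 left out, KO-2 is library 3 alone (n = 1) and its spread is borrowed from the other groups. In that fit 2 ribosomal, 0 hypoxia, 0 glycolysis, 1 p53 and 0 cholesterol genes rose, while 23 hepatic markers, 8 chaperones and 4 endothelial markers (median −0.65 against −0.76) fell. Without KO-2 library 3 instead, 16 hypoxia, 23 glycolysis, 13 p53 and 16 cholesterol genes rose.

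KO-2 gave 3990 genes past the threshold, 2123 higher and 1867 lower. That balance turned in other fits: 228 were higher and 563 lower with 6 libraries, 217 and 475 against a 1.5-fold minimum, 299 and 725 without the 3 libraries, 358 and 695 without KO-2 library 2 and 392 and 823 without WT library 1. The fit of the 6 KO-2 and WT libraries gave 791, the fit without the 3 libraries (n = 1 in KO-2) 1024, of which 734 were among the 3990, and a 1.5-fold minimum gave 692. Leaving out WT library 1, 2 or 3 gave 1215, 1704 or 1339, and leaving out KO-2 library 1, 2 or 3 gave 1140, 1053 or 11577.

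KO-3 gave the most genes past the threshold of the 3 clones, although without KO-2 library 3 KO-2 gave 11577 and KO-3 11539. Its cardiac genes were far lower: TBX20, a heart transcription factor, went from 277 ± 50 to 20.4 ± 7.0 CPM, RYR2, the sarcoplasmic calcium release channel, from 1144 ± 283 to 120 ± 45.6, and NPPA, the atrial natriuretic peptide, from 156 ± 4.2 to 4.65 ± 1.5 (log2 change −5.06 ± 0.33, adjusted p = 1e-06). Of 32 sarcomere genes 26 fell (29 adjusted over the list alone; median −2.69; camera adjusted p = 5.2e-17; adjusted p = 0.21 with an estimated correlation). Chaperones fell, 20 of 32 (23 fell and 1 rose adjusted over the list alone; camera adjusted p = 8.3e-08; adjusted p = 0.24 with an estimated correlation), with CRYAB, the alpha B crystallin of muscle, at −3.14 ± 0.27. Oxidative phosphorylation genes fell, 36 of 40, with 1 higher, the same numbers as adjusted over the list alone (camera adjusted p = 2.7e-16; adjusted p = 0.20 with an estimated correlation), and the share of counts from mitochondrial genes was 1.01% ± 0.319 against 2.12% ± 0.572 in WT. Hepatic markers fell by a median of 4.62, 24 of 26 with 1 risen (25 and 1 adjusted over the list alone; camera adjusted p = 1.1e-16; adjusted p = 0.20 with an estimated correlation).

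In the same clone, 23 of 31 cell cycle genes rose (24 adjusted over the list alone; camera adjusted p = 1.4e-09; adjusted p = 0.24 with an estimated correlation), including PLK1, a mitotic kinase (1.22 ± 0.18), and MCM2, a subunit of the replicative helicase (1.14 ± 0.17). Neural markers rose, 13 of 19 (13 adjusted over the list alone; camera adjusted p = 5.1e-06; adjusted p = 0.28 with an estimated correlation), as did 7 of 10 pluripotency markers (7 risen and 1 fallen adjusted over the list alone; camera adjusted p = 0.0020; adjusted p = 0.25 with an estimated correlation). NKX2-1, a factor of ventral forebrain, lung and thyroid, had 643 counts in KO-3 and 4 in WT, 168-fold higher at equal depth (95% exact interval 65.3 to 618). CBR1, a carbonyl reductase gene, had 0 counts in KO-3 and 182 in WT, at least 58.1-fold lower. KO-3 gave 8455 genes past the threshold, 3682 higher and 4773 lower. The count was 3569 against a 1.5-fold minimum and 12733 with KO-1 library 3 and KO-2 libraries 1 and 2 left out.

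Genes changed in all 3 clones in 1 direction numbered 703, with 187 higher and 516 lower. Independent calls would share 8.8 and 12.6. S100A6, HSPA8, FLT1 and HNF4A were among the shared falls and SOX2, PAX2 and FGF19 among the shared rises. Each clone was compared with the same WT libraries, which makes the 3 tests dependent. Against a 1.5-fold minimum 145 genes were shared. Without WT library 1, 2 or 3 the count was 313, 430 or 277, without KO-1 library 3 it was 409, and without KO-2 library 1 or 3 it was 446 or 1394.

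The clones were also tested against each other. They differed for 8777 genes, 36.4% of those tested. CFLAR, an inhibitor of death receptor signalling, was at 74.5 ± 9.9 CPM in KO-1, 68.6 ± 8.8 in KO-2 and 8.13 ± 1.6 in KO-3 (edgeR adjusted p = 1.8e-06 for any difference), and TRH, thyrotropin-releasing hormone, was at 88.3 ± 15 in KO-1 and 134 ± 27 in KO-2 and fell by 3.56 ± 0.21 in KO-3 against WT (adjusted p = 5.5e-06 between clones). C9orf64, a tRNA queuosine salvage gene, had 1 count in KO-1, 2 in KO-2 and 298 in KO-3, against 177 in WT (KO-1 over WT 0.00716, 95% exact interval 0.00018 to 0.0404). Against the mean of the other two, 366 genes differed in KO-1, 9315 in KO-2 and 6922 in KO-3. Without KO-2 library 2 or 3 the number of genes that differed between clones was 5312 or 15002.

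**Figure D3:**
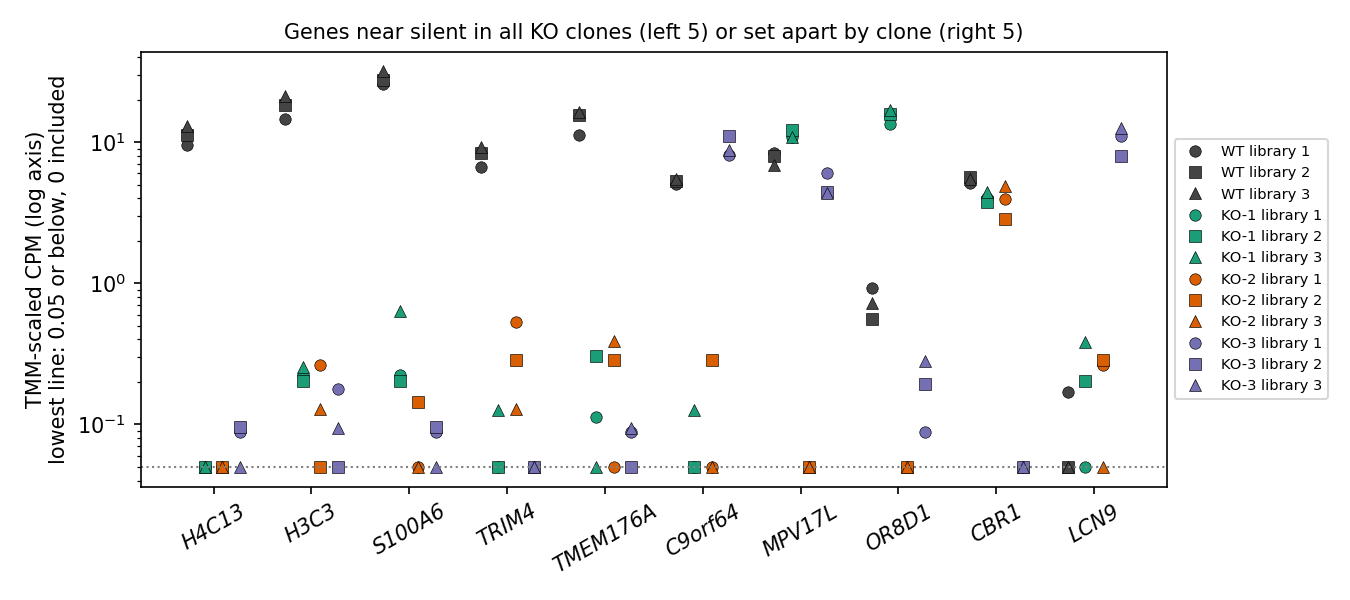
TMM-scaled CPM on a log axis for 10 genes in every library, with values of 0.05 or below, 0 included, drawn on the dotted line. The 5 genes on the left were near silent in all 9 KO libraries, and the 5 on the right were present or absent clone by clone, such as MPV17L with 0 counts in all 3 KO-2 libraries.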

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

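All tests in this part were chosen or written down only after the results they bear on had been seen, except the test between clones and the fit with the clone as a random block, which were fixed before the data were examined. The clones differed for 8777 genes, 36.4% of those tested, in the edgeR test on 2 degrees of freedom. Of the 79 genes followed one by one, 71 were among them. Some of the 79 were chosen for differing between clones or for a change in 1 clone, so that share partly restates the choice. For each of the 71, the distance between the highest and the lowest clone is given as a difference of log2 fold changes, n = 3 libraries per clone. It was 1.15 for HSF1, 0.70 for HSF2 and 2.95 for HSF4. Among chaperones it was 2.39 for HSPB8, 0.93 for HSPA8, 0.72 for HSPH1, 3.04 for CRYAB, 0.87 for HSPE1, 2.78 for HSPB3 and 3.07 for UNC45B. Cardiac and muscle genes gave 3.00 for MYOZ2, 2.22 for NEBL, 1.80 for TPM1, 3.31 for TBX20, 2.71 for HAND1, 3.68 for IRX4, 2.60 for HEY2, 5.74 for NPPA, 3.83 for MYL7, 2.57 for SLN, 2.95 for RYR2, 2.58 for SLC8A1 and 3.24 for CKM. Metabolic genes gave 1.38 for CPT1A, 1.64 for COX5B, 4.06 for COX6A2, 6.55 for GSTA2 and 1.89 for SLC2A1. Hepatic markers differed by 3.65 for HNF4A, 5.47 for APOC3, 4.01 for RBP4 and 2.89 for VTN, and endothelial or matrix genes by 1.33 for FLT1, 1.16 for KDR, 0.62 for CDH5, 1.55 for ENG, 1.18 for FN1, 1.83 for TGFBI and 2.19 for VEGFA. For neural and developmental genes the distance was 1.89 for SOX2, 2.30 for OTX2, 2.44 for FGF19, 2.44 for FGF3, 2.26 for PAX2, 2.35 for PAX5, 3.71 for VAX1, 3.22 for NR2E1, 3.78 for PANTR1, 1.25 for LIN28A and 1.02 for SALL4. Cell cycle genes gave 0.90 for PLK1 and 0.87 for MCM2. Cytokine and NF-kB genes gave 7.20 for CXCL2, 7.17 for CXCL3, 6.56 for ICAM1, 4.24 for TNFAIP3 and 3.49 for NFKBIA, and further genes 4.04 for GABRQ, 3.19 for CFLAR, 3.73 for PKIB and 3.43 for TRH. Where a clone had 3 counts or fewer in all, groups were read at a floor of 3 counts: the distance was then 1.54 for TRIM4, 6.09 for KNG1, 3.28 for SLC2A5, 6.57 for OR8D1, 6.36 for C9orf64, 6.14 for MPV17L, 6.95 for NKX2-1, 6.03 for LCN9, 5.45 for CBR1 and 4.86 for ACSM2A.

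Other splits of the libraries into groups of the same sizes were tested for each count. For the mean of the clones, 1 of 100 splits, the real one with 5055 genes, gave as many, and the highest other gave 3943. For the genes shared by all 3 clones (703) the highest other was 1, again 1 of 100 splits. For differences between clones (8777) it was 5334, also 1 of 100 splits. A random grouping of libraries is excluded at the 5% level for these counts. The splits exchanged single libraries and mixed clones, so for the mean and the shared genes they cannot exclude chance differences between lines. With the clone as a random block 158 genes passed in the mean. For KO-1, KO-2 and KO-3 the real splits gave 1480, 3990 and 8455 and the highest other gave 0 in each, 1 of 10 splits, and 10 splits are too few for a share under 0.05. The number of lists past the camera threshold in the mean was 23, which 44 of 100 splits reached or passed with up to 36 lists, so chance cannot be excluded for that number.

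NF-kB targets were high in KO-2 libraries 1 and 2, with list medians of 2.75 and 3.14 and ICAM1, an adhesion molecule, at 626 and 692 CPM against 8.39 in KO-2 library 3 and 6.74 to 8.45 in WT. Abundant leukocyte genes had a median of −0.60 in the higher of the 2 libraries, over the 5 of 12 genes measured. The low-count filter asked for enough counts in 3 libraries, so a leukocyte gene present only in these 2 would have been dropped. Leukocytes in these 2 libraries therefore cannot be excluded. HSF1 knockout alone is argued against because only 2 of 9 KO libraries had the NF-kB median above 1. They were the 2 with the highest HSF1 of all KO libraries (96.4 and 118 CPM). As for mislabelled libraries, at most 9.09% of the 22 WT markers and 0% of the 4 KO-1 markers were in that group's state. For the 25 KO-3 markers it was 24% in KO-2 library 1 and 12% in library 2, the first above the 20% set for that test. Of 128 markers of KO-2 libraries 1 and 2, 1 was in their state in KO-2 library 3. A further test, chosen after those percentages were seen, found 0 counts of MPV17L in KO-2 libraries 1 and 2. The mean KO-3 rate would put it at 18.7 and 34.6 counts. MPV17L was named for its fall in KO-2, so its 0 counts were known beforehand. This 1 gene therefore cannot decide whether they are libraries of KO-3. NKX2-1, LCN9 and C9orf64, named for changes in KO-3 or KO-1, had 2, 3 and 2 counts over all KO-2 libraries. In KO-3 they had 643, 341 and 298. These 3 genes, also seen beforehand, argue against libraries of KO-3, although the 24% of markers in library 1 stayed above its limit. A difference in culture or handling between KO-2 libraries may be the source, which the labels do not record and no test here reached.

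Hepatic markers fell and neural markers rose in the KO libraries. A lower share of cardiomyocytes would raise the markers of every other cell type, but the hepatic median was −2.92 and the endothelial −0.89, against 1.48 for neural markers, which argues against it as the whole cause. Library depth is argued against as well, since 23 of 26 hepatic markers fell and 10 of 18 neural markers rose with all libraries thinned to 1 total. With the clone as a random block 6 hepatic markers fell and 0 neural markers rose while the medians stayed large (−3.21 and 1.36), and differences between lines or differentiations cannot be told apart from loss of HSF1 because WT is 1 line. Both may contribute, and an effect of HSF1 on which cell types form stays an untested hypothesis.

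In 11 genes with at least 4 CPM in WT, every clone lay 16-fold or more below WT, while 0 genes showed the reverse. By the same rule 4 genes were present only in KO-1, 8 only in KO-2 and 6 only in KO-3. Genes low only in KO-1, KO-2 or KO-3 numbered 0, 1 and 6, so such genes were not particular to WT. Of the 11, 1 microRNA gene ranged from 14 to 642 counts in WT and from 0 to 29 in the KO libraries. Loss of hepatic-like cells is argued against because every hepatic marker kept at least 23.1% of its WT level in KO-1 (14.1% less 2 SE at the lowest), above the 6.25% that chose these genes. Loss of a chromosome segment that reaches the neighbours within 500 kb is argued against because the neighbours' median log2 change was −0.55 at its lowest and 0.81 at its highest. A difference between the WT line and the line that gave rise to the clones may have set these 11 genes apart, and it cannot be told apart from HSF1 loss because no second WT line was measured.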

How the results depend on the processing

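The fit without KO-1 library 3 and KO-2 libraries 1 and 2 was chosen after seeing the data, and all other alternatives were fixed before. Under DESeq2, RLE factors, factors without mitochondrial and abundant genes, no filter and a stricter filter, every total stayed within 1.5 times its reported value except KO-1 with DESeq2 (2239 against 1480); of the shared genes, 187 higher became 329 with DESeq2 and 281 with no filter. With DESeq2 and the other 2 sets of factors the median log2 change of all genes was at most 0.024 from 0. Against a 1.5-fold minimum the counts were 313 in KO-1, 692 in KO-2, 3569 in KO-3, 1163 in the mean and 145 in all 3 clones, lower because the test asks for a larger change. Fits of 6 libraries gave 2652 in KO-1 and 791 in KO-2. Without the 3 libraries, which leaves KO-2 with n = 1, KO-1 gave 2484, KO-2 1024 and KO-3 12733, with 1385, 734 and 8454 genes in common with the reported calls, all in the same direction. The mean gave 158 genes with the clone as a random block (correlation 0.489), 1079 with 2 groups, 9813 without KO-2 and 1284 without KO-3; the cause was not tested. HSF1 in the mean stayed past the threshold in 21 of 25 alternatives. It did not with the clone as a random block (−0.919), with 2 groups (−0.778), without KO-3 (−0.51) or against a 1.5-fold minimum (−0.851), with adjusted p values of 0.463, 0.148, 0.135 and 0.214. Of the 23 lists past the camera threshold in the mean, 0 passed with an estimated correlation, while fry passed 21 lists and camera with the replicate block 23.

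Leaving out each library in turn gave 558 to 3643 genes in KO-1, 1053 to 11577 in KO-2, 6394 to 11539 in KO-3, 2611 to 9339 in the mean, 277 to 1394 in all 3 clones and 5312 to 15002 between clones. HSF1 ranged from −0.926 to −0.769. All 6 highest counts came without KO-2 library 3. With replicate number as a block the counts were 1314, 3276 and 8058 for KO-1, KO-2 and KO-3, 4641 for the mean, 589 shared and 8140 between clones. Libraries of the same replicate number correlated by −0.11 to 0.13 after group means were removed, and 5 of 12 were closest to one of their own number, so no pairing was used.

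For single genes, 185 named changes were recomputed under the alternatives, 4530 values in all: 3880 were unchanged, 615 no longer passed, 30 newly passed and 5 turned. A value past the threshold in neither setting was counted as unchanged even if its sign changed. The 5 that turned were all in the mean of the clones: OR8D1 without KO-2 (1.225), CKM, muscle creatine kinase, without KO-3 (0.127), MYL7 without KO-3 (0.024), and SLC2A1, a glucose transporter, without KO-2 (−0.523) and without the 3 libraries (−0.488). Of 63 single genes called in the mean, 11 stayed past the threshold with the clone as a random block, namely GSTA2, H3C3, H4C13, HNF4A, KNG1, RBP4, S100A6, SLC2A5, SLN, TMEM176A and TRIM4, and 20 with 2 groups. Without KO-3, 35 of 61 stayed past it.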

Other observations

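Genes of the forebrain and eye field, a list of 26 written after the data were seen, rose in KO-3 (24 of 26) and KO-1 (16), and fewer passed in KO-2 (6). The list median was 3.28 in KO-1 library 3, 1.55 and 1.25 in KO-1 libraries 1 and 2, and 3.15 to 3.46 in KO-3. OTX2, a factor of anterior brain and eye, rose by 2.94 ± 0.35 in KO-3 and by 2.01 ± 0.34 in KO-1. NR2E1, a factor of neural stem cells, rose by 5.06 ± 0.78 in KO-3, and PANTR1, a noncoding RNA, by 5.25 ± 0.98. LIN28A and SALL4, regulators of pluripotent and early progenitor cells, rose in KO-3 by 1.98 ± 0.28 and 1.21 ± 0.17.

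In KO-3, 13 of 20 TGF-beta and BMP targets fell (13 adjusted over the list alone; camera adjusted p = 5.2e-05; adjusted p = 0.24 with an estimated correlation), as did 13 of 20 autophagy and lysosome genes (15 adjusted over the list alone; camera adjusted p = 1.3e-05; adjusted p = 0.28 with an estimated correlation). Replication-dependent histones rose in KO-3, 9 of 21 (9 adjusted over the list alone; camera adjusted p = 0.00019; adjusted p = 0.42 with an estimated correlation). In KO-2, 7 of 21 integrated stress response genes rose and 2 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.071), and 0 rose without KO-1 library 3 and KO-2 libraries 1 and 2, where KO-2 is 1 library. Notch and Wnt targets gave 7 risen and 2 fallen of 20 in the mean, the same adjusted over the list alone (camera adjusted p = 0.037; adjusted p = 0.33 with an estimated correlation). Genes of 20q11.21, a region often gained in stem cell cultures, gave 3 risen and 2 fallen of 20 in the mean (4 and 2 adjusted over the list alone; camera adjusted p = 0.63).

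Over 23 chromosomes the median log2 change of the genes lay between −0.04 and 0.06 in KO-1, −0.12 and 0.13 in KO-2 and −0.07 and 0.13 in KO-3. At equal depth KO-2 libraries 1 and 2 showed 30904 and 30287 genes with a count, against 33221 to 34448 in the other 10 libraries. TNFAIP3 and NFKBIA, both feedback inhibitors of NF-kB, were at 439 and 448 CPM and at 439 and 472 CPM in these 2 libraries, and at 31.1 and 40.3 in KO-2 library 3. ZC3HAV1L, a zinc finger gene, had 204 counts in WT and 0 in every KO library, at least 53.7-fold lower in KO-1, 37.4-fold in KO-2 and 65.1-fold in KO-3. PXMP4, a peroxisomal membrane protein gene, had 147 counts in WT and 2 in the KO libraries together (0.592% of the WT level, 95% exact interval 0.0711 to 2.18), and CCDC169 had 156 and 7 (1.95%, 0.772 to 4.12). Fold changes of KO-1 and KO-3 correlated across genes (r = 0.766), KO-1 and KO-2 at 0.425 and KO-2 and KO-3 at 0.407. Unchanged clones simulated against a common WT gave 0.489, 0.452 and 0.462, since the shared control alone correlates them. The observed covariance exceeded the simulated by 0.483, 0.178 and 0.317, and genes are not independent replicates.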
